A study of Mus musculus with 81 samples.

How the data were processed

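Bone marrow cells of male mice aged 6 weeks, per the labels, were sorted for CD11b and Ly6G, and each sample was a pool of mice, per the series design. RNA was extracted with TriZol, labelled with biotin using a WT Terminal Labeling kit and hybridised to Affymetrix whole-transcript arrays, per the labels' protocols. The submitters' processing notes name Affymetrix Power Tools and RMA, without versions, roles or order. The deposited values are probe set intensity values on a linear scale, made by the authors with these tools; that the scale is linear was read from the values themselves, which ran from 5.30 to 19348 with array medians between 97.2 and 114.8. The genome build and the annotation behind the probe sets are not given in the sources used here. The series design text gives a larger number of probes than the 24922 deposited, on which all shares here rest, and what was left out is not stated. No scanner files were used here, so probe-level signals and backgrounds were not examined.

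Every value was converted to log2 and not scaled further. Probe sets were named through the platform's gene table, which gave 1 symbol for 21425 probe sets, several for 1399 and none for 2098; only probe sets with 1 symbol were named. A gene with several probe sets was represented by the brightest, which left 19752 genes, of which 19677 had a gene identifier in the reference gene table of assembly GRCm38.p6, used for names and neighbour order alone. No 2 arrays were identical, with a highest correlation between arrays of 0.997. The probes of this array type follow the reference sequence of C57BL/6J, so a sequence variant under a probe can lower the measured intensity in other strains, and these values do not separate that from a lower transcript level.

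Samples were grouped by title into 40 groups, of which 5 are wild-derived and 35 classical by common knowledge of the strain names. In 5 groups with 10 arrays the title and the background label name different strains; both labels keep the arrays of each group together, and the title was used. Tests were run in R 4.3.3 with limma 3.58.1, with lmFit and eBayes on log2 values and Benjamini-Hochberg adjustment, and a probe set was called at an adjusted p under 0.05. Strain differences were tested with the moderated F statistic of a model with 1 mean per group over all 81 arrays, with 41 residual and 7.93 prior degrees of freedom, and additionally with a range of at least 2-fold between strain means. The same model gave the contrasts of C57BL/10J with C57BL/6J, CBA/J with CBA/CaJ, NOD/ShiLtJ with NOR/LtJ and NZB/BINJ with NZW/LacJ, and of each strain with C57BL/6J, the last with a difference of at least 1. Spread is pooled over all groups, so a group left with 1 array is taken to vary like the others. Wild-derived and classical strains were compared on strain means, with the strain as the replicate and 1 spread pooled over both origins. Differences are given as first strain minus second, and wild-derived minus classical.

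These tests, the fixed gene lists, the rule for naming genes and most alternatives were chosen before the data were examined. Named genes were the 25 with the largest SD of strain means among called genes with a highest strain mean of at least 7, the 10 higher and 10 lower genes with the largest difference between origins whose 5 wild-derived means lay on the same side of the classical median, and up to 6 higher and 6 lower genes per pair whose arrays did not overlap between the strains, each with the higher group's mean at least 7. In addition up to 4 members of each list, by size of difference or SD, and every polymorphic and sex-linked gene could be named.

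The 26 lists hold 312 entries, of which 260 matched a measured gene. They cover azurophil, specific and gelatinase granules, mature neutrophils, NADPH oxidase, cell cycle, interferon-stimulated genes, guanylate-binding and immunity-related GTPases, the Ifi200 family, class I and class II histocompatibility genes, pattern recognition, inflammasomes, inhibitory and Fc receptors, cytokine receptors, glutathione and redox enzymes, genes known to be polymorphic among strains, immediate early and stress genes, and sex-linked genes. Marker lists cover erythroid cells, B cells, T and NK cells, monocytes and macrophages, eosinophils, basophils and mast cells, and megakaryocytes. Lists were tested in limma's camera, 2-sided, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation. Member counts are given over all probe sets and adjusted over the list alone.

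Alternatives changed 1 choice at a time: quantile normalization, a common array median, a trended and robust variance prior, probe sets with a mean of at least 7, the replicate number as a block, each array left out, the groups of conflicting labels left out, grouping by background label, probe sets with a highest strain mean of at least 7, the groups of 1 array left out, each wild-derived strain left out, arrays with the strain as a random block, the arrays of a pair alone, another size threshold, and the mean over a gene's probe sets. The F test, the contrasts and the comparison of origins were tried on simulated data of 24922 probe sets with 200 changed. The list test was tried on 1 shifted list. Covariates, random splits and the test of neighbouring genes were not simulated. The F test recovered 100% of those changed with an SD of 0.5. At a difference of 1 the share recovered was 97.5% for C57BL/10J with C57BL/6J, 97% for the CBA substrains, 95.5% for NOD/ShiLtJ with NOR/LtJ, 97.5% for NZB/BINJ with NZW/LacJ and 96.5% for wild-derived with classical strains. For each strain against C57BL/6J, where the threshold equals the simulated difference, 48% were recovered at 1 and 100% at 2. At a difference of 1 false calls made up 6.25% of the calls for C57BL/10J with C57BL/6J and for NZB/BINJ with NZW/LacJ. The false share was 5.91% for NOD/ShiLtJ with NOR/LtJ, 4.43% for the CBA substrains and 3.02% for wild-derived with classical strains. For each probe set all arrays, and all strain means, were simulated with the same spread. In the real data the residual SD was 0.216 in NZB/BINJ arrays and 0.127 in NZW/LacJ arrays, and many named genes spread unequally within the 2 origins. The simulated shares need not hold for those comparisons. In the simulated list test the shifted list was called and 0 of 25 others were called by limma's camera. The genes were simulated as independent of each other. This test therefore says nothing about camera at the higher correlations estimated for some lists in the real data.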

Results

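Neutrophils were sorted from the bone marrow of 6-week-old male mice as cells carrying both CD11b and Ly6G, and their RNA was measured on 81 Affymetrix whole-transcript arrays. Sample titles put the arrays in 40 groups, 1 per inbred strain as titled, and each array held RNA pooled from several mice. C57BL/6J had 5 arrays. FVB/NJ and SWR/J had 1 array each, and the other 37 groups had 2. In 5 groups the title and the genetic background label named different strains. These groups, with 10 arrays, are called titled BPL, titled BTBR, titled Balb, titled C57BR and titled DBA2 and stand as separate groups. The deposited table holds 24922 probe sets for every array, fewer than the series design text gives, with array medians between 97.2 and 114.8 intensity units and single values between 5.30 and 19348. The number of arrays per strain limits the precision. All values below are log2 intensities, differences are differences of log2 intensity with their standard error (SE), and adjusted p-values come from limma with Benjamini-Hochberg adjustment.

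The first question set by the design was how far neutrophil transcripts differ among inbred strains. Chil3, a chitinase-like protein stored in neutrophil granules, had the largest spread of strain means. It stood at 13.02 ± 0.11 (SD, n = 2) in NON/ShiLtJ and at 4.08 ± 0.44 (SD, n = 2) in RIIIS/J, with an SD of 2.88 over the 40 strain means (adjusted p = 2.0e-47). The probe set that the platform's gene table assigns to Kcnma1 had a median strain mean of 5.41 and reached 13.70 ± 0.00 (SD, n = 2) in AKR/J. Kcnma1 is the pore-forming subunit of a calcium-activated potassium channel. Whether this probe set measures its transcript was not tested. Samd9l, an interferon-inducible gene, showed the opposite layout: the median strain mean was 11.15, and SEA/GnJ lay at 3.89 ± 0.39 (SD, n = 2). The transcript BC018473 spanned 5.34 in titled Balb to 12.61 in NZW/LacJ, with an SD over strains of 2.71.

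**Figure D1:**
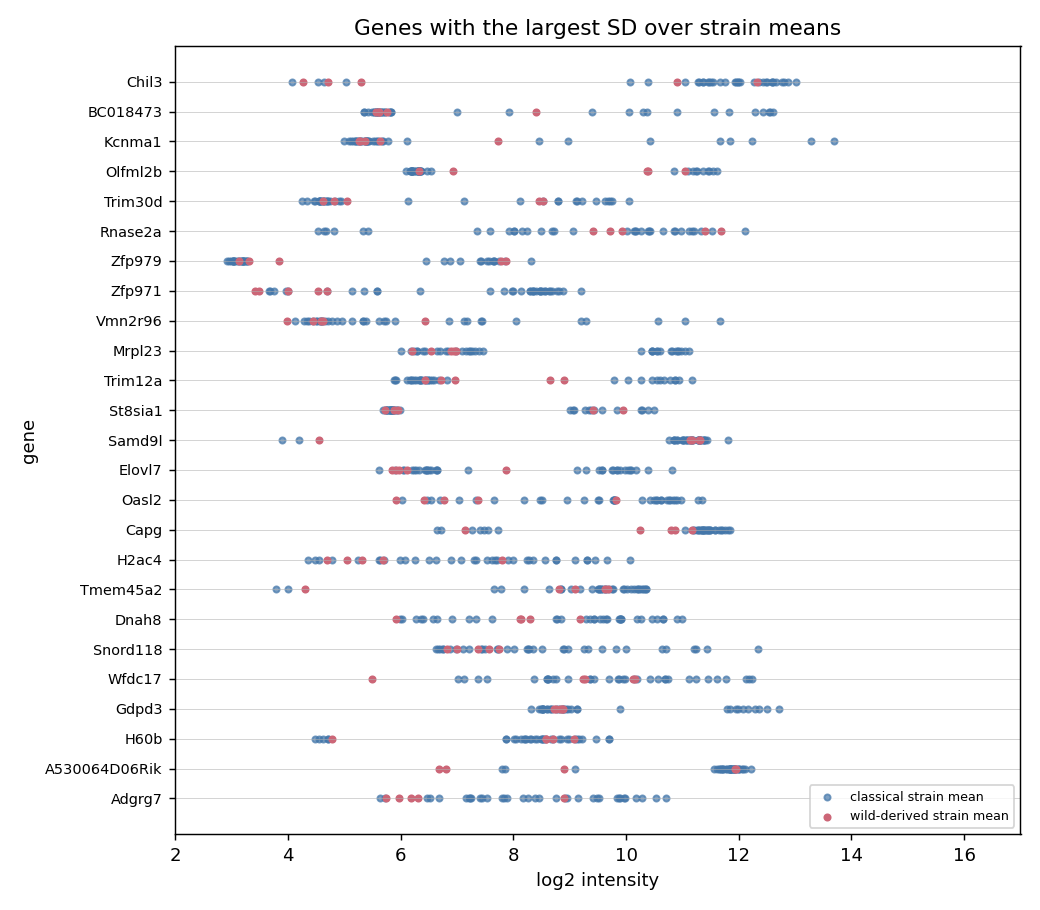
Strain means of the 25 genes with the largest SD over the 40 strain means, on the log2 intensity scale, with 1 point per strain and wild-derived strains in red. Chil3 ran from 4.08 to 13.02. For the probe set assigned to Kcnma1 most strains lay near the median of 5.41 while AKR/J lay at 13.70.

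Of the 24922 probe sets, 13964 (56.0%) differed among strains in limma's moderated F test, and 6113 of them (24.5% of all) did so with a range of at least 2-fold between the highest and the lowest strain mean. The range was at least 8-fold for 379. At an unadjusted p under 0.05 there were 15223. The share of variance lying between strains had a median of 33.7% over all probe sets and 55.2% over the 10816 probe sets whose mean was at least 7. Among the 25 genes with the largest spread were members of the tripartite-motif family: Trim30d ran from 4.24 in FVB/NJ (n = 1) to 10.04 in C57BLKS/J(662), and Trim12a from 5.88 in SWR/J (n = 1) to 11.18 in titled C57BR. Zinc-finger genes were present with Zfp979 (2.91 in titled BPL, 8.32 in NOD/ShiLtJ) and Zfp971 (3.42 in JF1/Ms, 9.21 in titled C57BR). St8sia1, the synthase of ganglioside GD3, lay between 5.69 in CBA/J and 10.50 in LP/J(676). Capg, an actin-capping protein, lay between 6.64 in KK.Cg-Ay/J and 11.84 in CBA/CaJ. Olfml2b, a secreted olfactomedin-like protein, lay between 6.10 in RIIIS/J and 11.62 in C57L/J (668). Rnase2a, an eosinophil-associated ribonuclease, ran from 4.53 in C57BLKS/J(662) to 12.11 in titled DBA2. The vomeronasal receptor gene Vmn2r96 ran from 3.99 in PWD/PHJ to 11.67 in P/J, and the replication-dependent histone H2ac4 from 4.36 in P/J to 10.07 in NON/ShiLtJ. Wfdc17 reached 12.24 in DDY/JclSidSeyFrkJ, and Gdpd3, a glycerophosphodiester phosphodiesterase, 12.71 in RIIIS/J. The other genes among the 25, with the SD of their strain means, were Mrpl23 (1.97), Elovl7 (1.81), Oasl2 (1.70), Tmem45a2 (1.61), Dnah8 (1.59), Snord118 (1.54), H60b (1.51), A530064D06Rik (1.5) and Adgrg7 (1.5).

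The counts of called list members below stand beside a high general share. Of all probe sets 56.0% were called, and 24.5% with a 2-fold range. Of the 10816 with a mean of at least 7, 9182 were called and 4601 with a 2-fold range. A high count of called members is therefore not particular to a list. Granule and maturation genes differed in spread. Of 12 measured specific granule genes, 9 were called over all probe sets and 9 when adjusted over the list alone, 6 of them with a range of at least 2-fold. Besides Chil3, Orm1 ran from 7.65 in JF1/Ms to 11.30 in titled BTBR, and Olfm4 from 9.87 in KK.Cg-Ay/J to 13.18 in P/J. Among 9 azurophil granule genes 8 were called (8 adjusted over the list alone) and 3 ranged at least 2-fold, led by Ms4a3, a gene of granulocyte-monocyte progenitors, between 5.59 in PWD/PHJ and 8.04 in NON/ShiLtJ. Of 7 genes in the gelatinase granule list 6 were called (7 adjusted over the list alone) and 1 ranged at least 2-fold. This was Arg2, an arginase, between 10.37 in PWD/PHJ and 11.94 in KK.Cg-Ay/J. Whether its product lies in these granules was not examined. Its SD over strains was 0.33, and the next largest of the list was 0.13 for Adam8. Arg2 had the lowest mean of the list, 11.44, while Mmp8 (13.52), Mmp9 (13.51) and Retnlg (13.42) lay near the highest values of the arrays, where compression of differences was not examined. For 11 genes of mature neutrophils, 10 were called (10 adjusted over the list alone) and 4 ranged at least 2-fold, among them Ccrl2 and the decoy interleukin-1 receptor Il1r2, with SDs over strains of 0.63 and 0.39. Of the 5 NADPH oxidase genes 3 were called (3 adjusted over the list alone), none with a 2-fold range; Cybb, the catalytic subunit, also at a high mean of 13.37, was not called (adjusted p = 0.11 in limma).

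All 17 measured cell-cycle genes were called, over all probe sets and adjusted over the list alone, and all 17 ranged at least 2-fold. Top2a, the DNA topoisomerase of dividing cells, lay at 10.35 ± 0.16 (SD, n = 2) in NON/ShiLtJ and at 6.45 ± 0.30 (SD, n = 2) in NOR/LtJ. The mean of the list ran from 6.91 in NOR/LtJ to 9.49 in NON/ShiLtJ, with an SD over strains of 0.68 against 0.21 between arrays of 1 strain. Interferon-stimulated genes formed a second widely spread group: 15 of 17 were called (15 adjusted over the list alone) and 13 ranged at least 2-fold. MSM/Ms had the lowest and C3H/HeJ the highest mean of this list, 6.64 and 8.87. The antiviral genes Oasl2 (5.92 and 11.34), Ifit3 (5.40 and 9.79) and Rtp4 (6.61 and 11.21) had these same strains as their lowest and highest. Guanylate-binding and immunity-related GTPases were called in 5 of 9 cases (5 adjusted over the list alone), 4 with a 2-fold range, led by Gbp7 between 6.36 in MSM/Ms and 9.58 in CE/J. In the Ifi200 family 4 of 5 were called (4 adjusted over the list alone), 3 with a 2-fold range, and Ifi203 stood at 9.38 in KK.Cg-Ay/J against 3.65 in FVB/NJ.

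**Figure D2:**
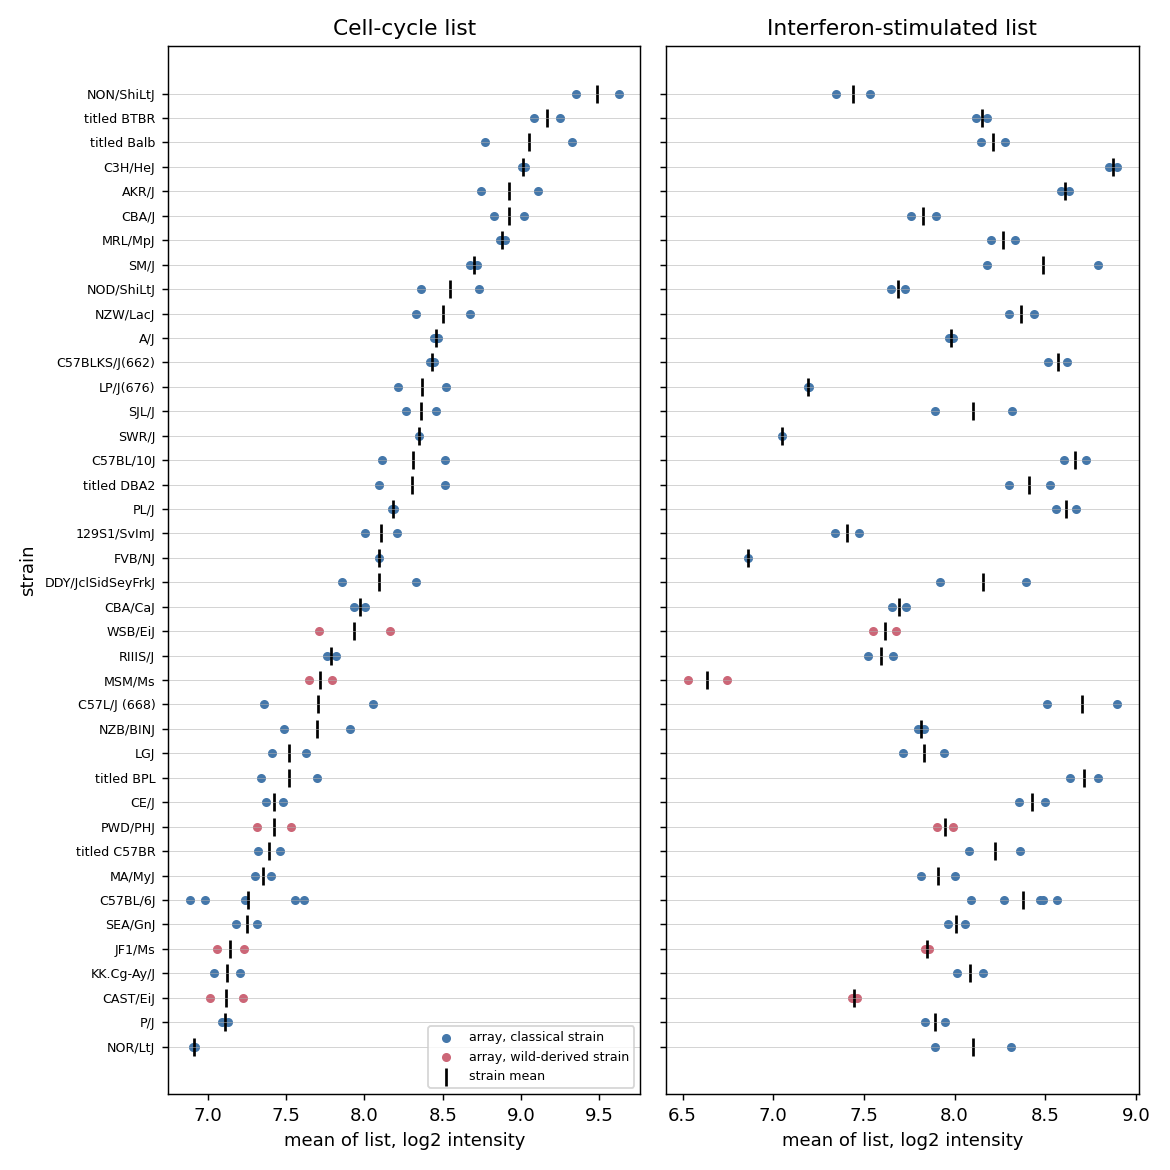
Mean log2 intensity of the cell-cycle list (left) and of the interferon-stimulated list (right) for each array, with strain means as bars and strains ordered by the cell-cycle mean. Cell-cycle means ran from 6.91 in NOR/LtJ to 9.49 in NON/ShiLtJ, and interferon-stimulated means from 6.64 in MSM/Ms to 8.87 in C3H/HeJ.

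Sensors of microbial products were all called, but so were 9182 of the 10816 probe sets with a mean of at least 7. All 16 pattern recognition genes were called (16 adjusted over the list alone) and 12 ranged at least 2-fold. Cd14, the co-receptor for lipopolysaccharide, reached 10.91 in SWR/J (n = 1) and lay at 6.26 in titled C57BR, and Tlr1 ran from 4.86 in CBA/CaJ to 7.98 in DDY/JclSidSeyFrkJ. The 13 inflammasome genes were all called (13 adjusted over the list alone), 11 with a 2-fold range. Naip5, a sensor of bacterial flagellin, lay at 4.41 in PWD/PHJ and 9.26 in SEA/GnJ, and Naip2 at 5.72 in PWD/PHJ and 10.49 in titled C57BR. Class I histocompatibility genes were called in 10 of 10 cases (10 adjusted over the list alone), 4 with a 2-fold range, with H2-Q10 between 6.08 in NOD/ShiLtJ and 9.50 in P/J. Class II genes were called in 7 of 9 (7 adjusted over the list alone), 4 with a 2-fold range, and Cd74, the invariant chain, lay highest in 129S1/SvImJ at 8.43. Of 14 inhibitory and Fc receptors 13 were called (13 adjusted over the list alone), 4 with a 2-fold range; Cd300ld reached 12.40 in PWD/PHJ and lay at 8.46 in titled Balb. All 15 cytokine receptors were called (15 adjusted over the list alone), 6 with a 2-fold range, and Il10ra ran from 6.73 in SEA/GnJ to 10.21 in JF1/Ms. Among 11 glutathione and redox genes 9 were called (9 adjusted over the list alone), 7 with a 2-fold range, with Gclm, a subunit of the glutathione-making ligase, between 8.12 in SM/J and 10.53 in DDY/JclSidSeyFrkJ and the quinone reductase Nqo1 between 5.36 in MSM/Ms and 8.41 in WSB/EiJ. Immediate early and stress genes were called in 12 of 13 cases (12 adjusted over the list alone), 8 with a 2-fold range, and Jun ran from 6.59 in C3H/HeJ to 9.14 in MRL/MpJ.

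A list of 14 measured genes known to differ in sequence or function among strains gave 13 calls (14 adjusted over the list alone), 6 with a 2-fold range. The SDs of their strain means were 0.72 for Nlrp1b, 0.63 for Gbp2b, 0.44 for Apobec3, 0.33 for Fcgr2b, 0.32 for Nnt, 0.28 for H2-Ea, 0.27 for Wdfy1, 0.18 for Raly, 0.17 for Ifi202b, 0.15 for Cd72, 0.14 for Hc, 0.10 for Mx1 and 0.09 for Itpr3. The agouti gene, with 0.13, was not called (adjusted p = 0.078 in limma).

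Markers of other bone marrow cells were measured in the same arrays. Monocyte and macrophage markers were called in 8 of 9 cases (8 adjusted over the list alone), 6 with a 2-fold range, and the complement gene C1qb lay between 6.44 in WSB/EiJ and 9.47 in titled BTBR. T and NK cell markers were called in 3 of 9 (3 adjusted over the list alone), all 3 with a 2-fold range. Cd3d reached 10.23 in FVB/NJ (n = 1) and lay at 6.20 in titled C57BR. Cd3g reached 8.41 in FVB/NJ, and Nkg7 ran from 5.82 in CAST/EiJ to 8.21 in NON/ShiLtJ. Of 9 B-cell markers 4 were called (3 adjusted over the list alone), 1 with a 2-fold range, and of 5 erythroid markers 3 (3 adjusted over the list alone), 1 with a 2-fold range. For eosinophils 3 of 6 were called (3 adjusted over the list alone), 2 with a 2-fold range, with Ear6 at 9.58 in WSB/EiJ against 6.48 in CBA/J. Among 7 basophil and mast cell markers Kit alone was called (1 adjusted over the list alone), between 5.99 in JF1/Ms and 8.91 in FVB/NJ (n = 1). Of 4 megakaryocyte markers 2 were called (3 adjusted over the list alone), both with a 2-fold range, and Ppbp, a platelet chemokine, reached 9.84 ± 2.36 (SD, n = 2) in NOD/ShiLtJ. The 4 sex-linked genes were called (4 adjusted over the list alone), 3 with a 2-fold range. Xist, which silences an X chromosome in females, had a mean of 5.31, and the Y-linked Eif2s3y, Uty and Kdm5d had means of 9.97, 7.96 and 7.85, each with its lowest strain mean in NZB/BINJ (8.65, 6.50 and 6.93).

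A comparison by origin set 5 strains derived from wild mice (CAST/EiJ, JF1/Ms, MSM/Ms, PWD/PHJ and WSB/EiJ) against 35 classical strains, with 1 mean per strain. Perp, a membrane protein of cell junctions that p53 induces, was the most different gene. It stood at 10.01 ± 0.56 (SD, n = 5) in wild-derived and 6.20 ± 0.36 (SD, n = 35) in classical strains. This is a difference of 3.81 ± 0.18 (SE; limma, adjusted p = 2.8e-19), with all 5 wild-derived strains above the classical median. Adgrg6, an adhesion G protein-coupled receptor, was higher by 2.97 ± 0.38, the tetraspanin Tspan15 by 2.88 ± 0.45, and Pfkfb2, an enzyme setting the level of a glycolysis activator, by 2.25 ± 0.30, with WSB/EiJ (7.78) near the classical mean of 7.30. Ibtk, an inhibitor of Bruton tyrosine kinase, was lower in wild-derived strains, with a difference of -2.66 ± 0.25, although WSB/EiJ at 9.52 lay near the classical mean of 9.59. The stefin Stfa3, a cysteine protease inhibitor, differed by -2.39 ± 0.46, with WSB/EiJ (7.67) near the classical mean of 7.89. Plac8 differed by -1.78 ± 0.24, with CAST/EiJ (9.69) near the classical mean of 9.86.

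In all, 1656 probe sets were higher and 1383 lower in wild-derived strains (54.5% higher), 3039 together, of which 87 and 114 differed at least 2-fold. Among probe sets with a mean of at least 7 the balance turned, with 43.7% of the calls higher. At an unadjusted p under 0.05 there were 6637. Without MSM/Ms the count was 1796 and without JF1/Ms 1971. Further higher genes were Plaat3, a phospholipase, by 2.05 ± 0.40, the monoamine oxidase Maob by 1.98 ± 0.35, the vanin Vnn3 by 1.95 ± 0.28, the lectin Clec9a by 1.76 ± 0.47, the carboxypeptidase Scpep1 by 1.75 ± 0.23 and Ms4a8a by 1.70 ± 0.21. Plaat3 stood at 11.44 in JF1/Ms and 10.42 in MSM/Ms, but between 6.04 and 6.27 in the other 3. Other differences were not shared by all 5 wild-derived strains either. For Scpep1, WSB/EiJ (5.51) and CAST/EiJ (5.74) lay near the classical mean of 5.51, for Ms4a8a WSB/EiJ (6.97) and PWD/PHJ (7.18) near 6.86, for Clec9a CAST/EiJ (6.94) and WSB/EiJ (7.10) near 6.65, and for Maob WSB/EiJ (5.48) near 5.25. Further lower genes were Zfp971 (-3.23 ± 0.81), the G protein regulator Rgs3 (-1.89 ± 0.24), the gluconeogenic enzyme Fbp1 (-1.88 ± 0.39), Lilra6 (-1.80 ± 0.50), the decoy receptor Tnfrsf23 (-1.72 ± 0.44), the adhesion molecule L1cam (-1.65 ± 0.34) and Emilin2 (-1.63 ± 0.20). For Rgs3, CAST/EiJ (10.31) and WSB/EiJ (10.40) lay near the classical mean of 10.63, and for Emilin2 WSB/EiJ did (10.76 and 10.77). For Lilra6, WSB/EiJ (11.96) lay above the classical mean of 11.76 and CAST/EiJ (11.44) near it, and for Tnfrsf23 CAST/EiJ (8.31) lay near the classical mean of 8.44. The difference of Clec9a was 1.53 without JF1/Ms and 1.38 without MSM/Ms, and that of Lilra6 -1.35 without MSM/Ms and -1.39 without PWD/PHJ; all 4 missed the threshold.

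**Figure D3:**
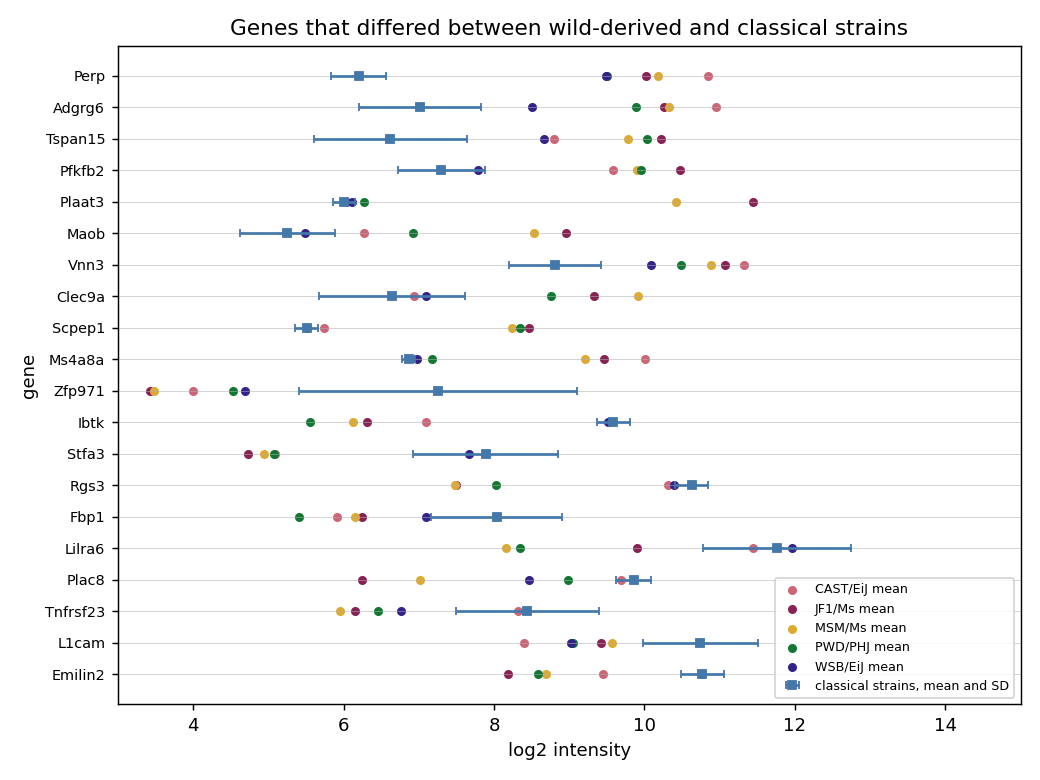
Log2 intensity of the 10 higher and 10 lower genes with the largest differences between origins, with 1 point per wild-derived strain mean and the mean and SD of the 35 classical strain means. All 5 wild-derived strains lay above the classical mean of 6.20 for Perp, and WSB/EiJ lay close to the classical mean for Ibtk, Stfa3 and Emilin2.

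Among the fixed lists, limma's camera called cell-cycle genes lower in wild-derived strains at the preset correlation (adjusted p = 2.0e-06). With the estimated correlation, 0.863, camera did not call the list (adjusted p = 0.594). Over 15 alternatives its adjusted p ran from 3.8e-07 to 0.594. The wild-derived list means, from 7.12 in CAST/EiJ to 7.93 in WSB/EiJ, lay inside the classical range of 6.91 in NOR/LtJ to 9.49 in NON/ShiLtJ. The median difference of the 17 cell-cycle genes was -0.68. On their own 2 passed (3 adjusted over the list alone), among them the replication clamp Pcna at -1.13 ± 0.31. In the same comparison Ms4a3 differed by -0.85 ± 0.26, the 1 called of 9 azurophil genes (1 adjusted over the list alone), whose median was -0.13 (list adjusted p = 0.0982). Kit, a receptor of mast cells and progenitors, differed by -1.54 ± 0.21, the 1 called of 7 basophil and mast cell markers (1 adjusted over the list alone). Specific granule genes were lower (adjusted p = 0.010; adjusted p = 0.242 with an estimated correlation; 0.00468 to 0.242 over 15 alternatives, with 0.145 under quantile normalization and 0.103 among probe sets with a mean of at least 7), with 5 of 12 lower over all probe sets and, adjusted over the list alone, 5 lower and 1 higher. Chil3 differed by -3.59 ± 1.22, Orm1 by -1.24 ± 0.32 and Ceacam10 by -0.68 ± 0.16. Interferon-stimulated genes were lower (adjusted p = 0.0119; adjusted p = 0.594 with an estimated correlation; 0.00888 to 0.594 over 15 alternatives, with 0.0662 among probe sets with a mean of at least 7), with 4 of 17 lower (4 adjusted over the list alone). The antiviral synthetase genes among them were Oasl2 (-2.20 ± 0.72), Oas2 (-1.51 ± 0.42) and Oas3 (-1.41 ± 0.34). Class I histocompatibility genes were lower at adjusted p = 0.0442 (adjusted p = 0.332 with an estimated correlation; 0.0255 to 0.332 over 15 alternatives), with 1 of 10 called by limma, H2-Q4 (-1.02 ± 0.35), 0 adjusted over the list alone, and 4 at an unadjusted p under 0.05. The class I call was lost under quantile normalization (0.145), among probe sets with a mean of at least 7 (0.289) and with the replicate number as a block (0.0599). It was lost as well without CAST/EiJ replicate 3 (0.0847), JF1/Ms replicate 2 (0.0830), MSM/Ms replicate 2 (0.0799) or PWD/PHJ replicate 2 (0.0664). The call of H2-Q4 was lost without CAST/EiJ replicate 3, JF1/Ms replicate 2, MSM/Ms replicate 2 or WSB/EiJ replicate 1, where its difference was -1.01, -0.99, -0.92 and -0.99. Leaving out whole strains ended further calls. Without JF1/Ms these were those of H2-Q4 (-0.80), Ms4a3 (-0.83), Chil3 (-2.78), Orm1 (-0.92), Pcna (-1.02) and Oasl2 (-1.99). Without MSM/Ms they were those of H2-Q4 (-0.81), Ms4a3 (-0.82), Chil3 (-3.04), Orm1 (-0.96), Ceacam10 (-0.51), Oasl2 (-1.86), Oas2 (-1.22) and Oas3 (-0.996). Without PWD/PHJ they were those of H2-Q4 (-1.12), Ms4a3 (-0.82), Chil3 (-2.90) and Oasl2 (-2.23). Without CAST/EiJ they were those of Oasl2 (-2.08) and Oas2 (-1.22), and without WSB/EiJ those of H2-Q4 (-1.01) and Oas2 (-1.30). Without the 5 groups of conflicting labels Chil3 (-3.51), Oasl2 (-2.13) and H2-Q4 (-0.98) were not called.

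The remaining lists were not called between origins, with adjusted p of 0.0736 or more, but single members were. Il10ra, the interleukin-10 receptor, was higher by 1.59 ± 0.38, and of 15 cytokine receptors 2 were higher (3 adjusted over the list alone). Of 16 pattern recognition genes 2 were higher and 4 lower (2 and 6 adjusted over the list alone). Tlr8 was higher by 0.58 ± 0.12 while Tlr7, another sensor of single-stranded RNA, was lower with -0.77 ± 0.11. Inflammasome genes gave 3 lower of 13 (3 adjusted over the list alone), with Il18 at -0.68 ± 0.14. Arg2, of the gelatinase granule list, differed by -0.70 ± 0.11, the inhibitory receptor Clec12a by -0.40 ± 0.09, the stress gene Atf3 by -0.40 ± 0.10 and the class II gene H2-Oa by 0.29 ± 0.06, each the 1 called gene of its list (1 adjusted over the list alone). Gclm, at -0.80 ± 0.22, was 1 of 3 lower glutathione and redox genes among 11 (1 higher and 3 lower adjusted over the list alone), and missed the threshold without MSM/Ms (-0.73) or PWD/PHJ (-0.62). Csf1r, the receptor of macrophage growth factor, was higher by 0.45 ± 0.11. It was the 1 higher gene among 9 monocyte and macrophage markers, of which 1 was lower (1 and 2 adjusted over the list alone), with a median of -0.09. The lower gene, the adhesion molecule Vcam1 (-0.69 ± 0.22), was not called without JF1/Ms (-0.67), MSM/Ms (-0.59) or WSB/EiJ (-0.62). Median, mean and test differed in sign for the gelatinase granule, NADPH oxidase, inhibitory and Fc receptor, B-cell, eosinophil, basophil and polymorphic lists, none of them called.

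The next comparison counted, for each strain, the probe sets at least 2-fold different from C57BL/6J, the strain on which the mouse reference genome is based. MSM/Ms had the most, 745, followed by NON/ShiLtJ with 711, JF1/Ms with 705, PWD/PHJ with 700 and CAST/EiJ with 688. C57BL/10J had the fewest, 136, followed by titled C57BR with 140 and NOR/LtJ with 207. Over 39 strains the median was 361, with medians of 700 over the 5 wild-derived and 325.5 over the classical strains, but the wild-derived WSB/EiJ had only 383. Without a minimum difference the median was 2155, the lowest count 661 and the highest 11120. All 39 contrasts share the 5 C57BL/6J arrays, so no overlap between them was computed. The mean of the cell-cycle list was 7.25 in C57BL/6J. It was 8.31 in C57BL/10J, 7.39 in titled C57BR and 6.91 in NOR/LtJ, against 9.49 in NON/ShiLtJ and 7.72 in MSM/Ms. How far the counts follow this level was not tested. Leaving out C57BL/10J replicate 3 lowered the lowest count to 66, and leaving out NZB/BINJ replicate 2 raised the highest to 1505.

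**Figure D4:**
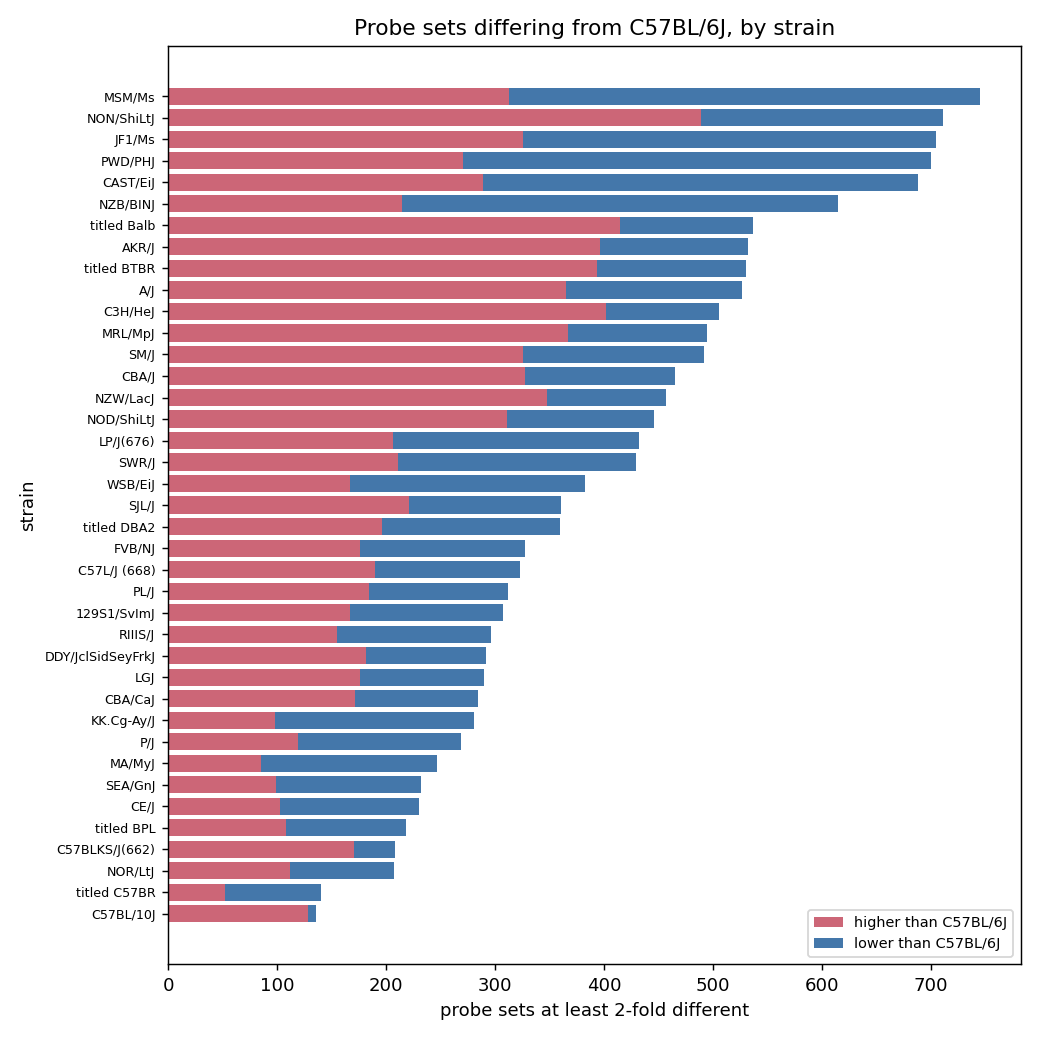
Number of probe sets at least 2-fold higher (red) or lower (blue) than in C57BL/6J, for each of 39 strains, called with limma at an adjusted p under 0.05. Counts ran from 136 in C57BL/10J to 745 in MSM/Ms.

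C57BL/10J and C57BL/6J are close relatives. The histone gene H2ac4 stood at 9.09 ± 0.27 (SD, n = 2) in C57BL/10J against 5.71 ± 0.83 (SD, n = 5) in C57BL/6J, a difference of 3.38 ± 0.47 (SE; limma, adjusted p = 1.5e-06). Of the other named genes, the histone H2bc3 was higher by 1.96 ± 0.30 and the linker histone H1f5 by 1.91 ± 0.25. Utp4, a factor of ribosomal RNA processing, was higher by 1.87 ± 0.11 (adjusted p = 3.9e-18) and Snord118, the U8 small nucleolar RNA, by 3.02 ± 0.52. Lower in C57BL/10J were the transcription factor Nfia (-1.54 ± 0.15), Nipal3 (-1.11 ± 0.11), the calcium-binding Efhd2 (-1.06 ± 0.10) and Scrg1 (-0.97 ± 0.13). Top2a (1.95 ± 0.34), Tas2r143 (-1.07 ± 0.27) and Itga8 (-0.95 ± 0.22) completed the named genes. Without C57BL/10J replicate 3 they differed by 1.56, -0.79 and -0.59 and were not called, and without C57BL/6J replicate 3 Tas2r143 differed by -0.94 and was not called. Cell-cycle genes were higher as a group (camera, adjusted p = 9.4e-33; adjusted p = 0.00277 with an estimated correlation; 1.3e-37 to 0.00277 over 12 alternatives). Here 13 of 17 were higher (15 adjusted over the list alone), with a median difference of 1.28, including Ccna2 (1.78 ± 0.29), Ccnb2 (1.60 ± 0.23) and Rrm2 (1.59 ± 0.24). In total 470 probe sets were higher and 191 lower (71.1% higher), 128 and 8 of them at least 2-fold, against 3661 at an unadjusted p under 0.05. After quantile normalization 52.5% of the calls were higher. The count of 661 became 999 without C57BL/10J replicate 1, 123 without C57BL/10J replicate 3, 420 without C57BL/6J replicate 3 and 117 with the mean of the cell-cycle list as a covariate, where H2ac4 (1.81), H2bc3 (1.08), H1f5 (1.13), Tas2r143 (-0.79) and Itga8 (-0.81) were not called. With the arrays of these strains alone the count was 297, and Itga8 was not called.

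Other lists called in this pair had few members past the threshold. Interferon-stimulated genes were higher by camera (adjusted p = 0.000350; adjusted p = 0.332 with an estimated correlation; 2.0e-05 to 0.332 over 12 alternatives), 15 of 17 with a positive difference, but 0 members were called by limma (1 adjusted over the list alone), against 6 at an unadjusted p under 0.05. Immediate early and stress genes were higher (adjusted p = 0.000838; adjusted p = 0.244 with an estimated correlation; 4.5e-07 to 0.247 over 12 alternatives), with 1 of 13 called (2 adjusted over the list alone), Junb at 0.63 ± 0.17. The 4 sex-linked genes were lower (adjusted p = 0.0130; adjusted p = 0.186 with an estimated correlation; 0.00490 to 0.186 over 12 alternatives), with 0 called by limma (2 adjusted over the list alone) and 2 at an unadjusted p under 0.05. Without C57BL/10J replicate 1 the interferon (0.0708), immediate early (0.247) and sex-linked (0.0548) calls were lost, and without C57BL/10J replicate 3 the sex-linked call (0.0802); Junb was not called without C57BL/10J replicate 1, where it differed by 0.24, or C57BL/6J replicate 1, where it differed by 0.55. In this pair Ms4a3 was higher by 0.68 ± 0.20, the 1 called of 9 azurophil genes (1 adjusted over the list alone), of which 6 were positive (list adjusted p = 0.0878). The call was lost without C57BL/10J replicate 3 (0.43) and without C57BL/6J replicate 1 (0.63), 2 (0.65), 3 (0.68) or 5 (0.70). Nnt, which C57BL/6J carries in a shortened form, was higher in C57BL/10J by 0.59 ± 0.12, and by 0.59 without C57BL/10J replicate 3 too, where it was not called. Median, mean and test differed in sign for the mature neutrophil, cytokine receptor and Ifi200 lists, none of them called.

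CBA/J and CBA/CaJ are substrains. Olfml2b was the most different gene, at 11.37 ± 0.00 (SD, n = 2) in CBA/J and 6.19 ± 0.01 (SD, n = 2) in CBA/CaJ, a difference of 5.18 ± 0.16 (SE; limma, adjusted p = 9.9e-31). St8sia1 was lower in CBA/J, 5.69 ± 0.09 against 10.26 ± 0.22 (SD, n = 2 each; difference -4.57 ± 0.18). H60b, a ligand of the natural killer receptor NKG2D, was higher by 3.31 ± 0.24, Plekhg1 by 2.50 ± 0.17, Itpripl1 by 2.01 ± 0.12, the aspartic protease Ctse by 1.94 ± 0.13 and the mitochondrial ribosomal protein gene Mrps5 by 1.89 ± 0.14. Lower were the peptide transporter Slc15a2 (-2.64 ± 0.24), Coro2a (-1.69 ± 0.15), Lactb2 (-1.61 ± 0.19) and Lgr4 (-1.60 ± 0.23). Of 13 inflammasome genes 1 was higher and 2 lower (1 and 2 adjusted over the list alone). They were Nlrp1b by 1.62 ± 0.19, Nlrp1a with -1.75 ± 0.26, and Casp4, a caspase activated by lipopolysaccharide, with -1.21 ± 0.15. Cell-cycle genes were higher in CBA/J as a group (camera, adjusted p = 1.2e-21; adjusted p = 0.0315 with an estimated correlation; 1.8e-23 to 0.0315 over 9 alternatives), with 8 of 17 called (17 adjusted over the list alone), a median difference of 0.96 and Bub1, a mitotic checkpoint kinase, at 1.81 ± 0.30. In total 284 probe sets were higher and 141 lower, 91 and 31 of them at least 2-fold, against 2930 at an unadjusted p under 0.05. The total of 425 became 182 and 190 without CBA/CaJ replicate 1 and 2, 124 and 214 without CBA/J replicate 1 and 2, 1185 with the arrays of these substrains alone and 116 with the cell-cycle mean as a covariate.

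Gelatinase granule genes were lower in CBA/J by camera (adjusted p = 0.0301; adjusted p = 0.512 with an estimated correlation; 0.00785 to 0.512 over 9 alternatives), with 0 of 7 called by limma (0 adjusted over the list alone) and 3 at an unadjusted p under 0.05. Cytokine receptors were lower too (adjusted p = 0.0187; adjusted p = 0.593 with an estimated correlation; 0.00432 to 0.593 over 9 alternatives), with 1 of 15 called (1 adjusted over the list alone), the chemokine receptor Cxcr4 at -0.41 ± 0.11, which missed the threshold without any 1 of the 4 arrays (-0.46 to -0.37). Both list calls were lost under quantile normalization (0.311 and 0.197), among probe sets with a mean of at least 7 (0.185 each), without CBA/CaJ replicate 2 (0.105 and 0.0816) and without CBA/J replicate 1 (0.241 and 0.234), and the gelatinase call also without CBA/CaJ replicate 1 (0.0582). Median, mean and test differed in sign for the glutathione, polymorphic, erythroid, monocyte and basophil lists, none of them called.

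NOD/ShiLtJ develops autoimmune diabetes and NOR/LtJ is a related strain that resists it. Zfp979 was the most different gene, at 8.32 ± 0.24 (SD, n = 2) in NOD/ShiLtJ and 3.28 ± 0.06 (SD, n = 2) in NOR/LtJ, a difference of 5.04 ± 0.24 (SE; limma, adjusted p = 3.6e-22). Trim12a was lower in NOD/ShiLtJ, 5.92 ± 0.03 against 10.61 ± 0.12 (SD, n = 2 each; difference -4.69 ± 0.18), as were Vmn2r96 (-3.87 ± 0.29), the inflammasome sensor Nlrp1a (-2.77 ± 0.26), Wfdc17 (-2.54 ± 0.53) and Cxcr1, an interleukin-8 receptor (-1.98 ± 0.16). Higher in NOD/ShiLtJ were Top2a by 2.74 ± 0.41, the ribonucleotide reductase subunit Rrm1 by 2.69 ± 0.32 and H2ac4 by 2.85 ± 0.56, together with Gm4759 by 2.65 ± 0.24. Snora44 (-2.12 ± 0.63) was called with all arrays but not without NOD/ShiLtJ replicate 1, NOD/ShiLtJ replicate 2 or NOR/LtJ replicate 2 (-2.58 to -1.67 over the left-out arrays), nor after centring on a common median (-2.05). Cell-cycle genes were higher as a group (camera, adjusted p = 1.6e-41; adjusted p = 0.000495 with an estimated correlation; 9.8e-44 to 0.000495 over 9 alternatives). Here 14 of 17 were higher (16 adjusted over the list alone), with a median of 1.68, including Ccna2 (2.58 ± 0.35), Ccnb2 (2.46 ± 0.28) and the proliferation marker Mki67 (2.37 ± 0.34). Ms4a3 was higher by 1.11 ± 0.24, a call lost without NOD/ShiLtJ replicate 1 (0.96). It was the 1 called of 9 azurophil genes (1 adjusted over the list alone), of which 3 were positive, with a median of -0.07 (list adjusted p = 0.449). In total 761 probe sets were higher and 624 lower (54.9% higher), 241 and 42 of them at least 2-fold, against 5167 at an unadjusted p under 0.05. Of the calls 65.4% were higher after quantile normalization, 75.1% after centring on a common median, 30.5% without NOR/LtJ replicate 1 and 84.6% without NOR/LtJ replicate 2. The total of 1385 became 451 without NOD/ShiLtJ replicate 1, 896 without NOD/ShiLtJ replicate 2, 708 without NOR/LtJ replicate 2, 815 with the arrays of these strains alone and 82 with the cell-cycle mean as a covariate, where H2ac4 (0.42), Rrm1 (0.20), Wfdc17 (-1.65) and Snora44 (-1.90) were not called.

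Megakaryocyte markers were higher in NOD/ShiLtJ (camera, adjusted p = 0.000116; adjusted p = 0.0721 with an estimated correlation; 3.7e-16 to 0.388 over 8 alternatives). All 4 were positive, with a median of 0.55, and Ppbp was the 1 called (3 adjusted over the list alone). Ppbp differed by 3.92 ± 0.50, by 2.25 without NOD/ShiLtJ replicate 2, where the list was not called, and by 5.59 without NOD/ShiLtJ replicate 1. The list was not tested without Ppbp. Specific granule genes were higher (adjusted p = 0.00184; adjusted p = 0.411 with an estimated correlation; 0.000549 to 0.411 over 9 alternatives, with 0.0992 under quantile normalization), with 2 of 12 called (3 adjusted over the list alone), Orm1 at 1.56 ± 0.27 and Chil3 at 0.78 ± 0.19, the latter lost without either NOD/ShiLtJ array (0.75 to 0.81 over the left-out arrays). Interferon-stimulated genes were lower (adjusted p = 0.0220; adjusted p = 0.676 with an estimated correlation; 0.00189 to 0.676 over 9 alternatives), with 3 of 17 called (3 adjusted over the list alone), among them the apoptosis-linked Xaf1 at -1.58 ± 0.24; the list call was lost without NOD/ShiLtJ replicate 2 (0.170) or NOR/LtJ replicate 2 (0.524). With the cell-cycle mean as a covariate Orm1 (0.95) and Xaf1 (-1.37) were not called. Median, mean and test differed in sign for the azurophil, gelatinase granule, Ifi200, T and NK cell, monocyte and eosinophil lists, none of them called.

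NZB/BINJ and NZW/LacJ are the parental strains of the lupus-prone New Zealand hybrid. Pi16, a peptidase inhibitor, was higher in NZB/BINJ, 10.14 ± 0.03 against 7.14 ± 0.06 (SD, n = 2 each), a difference of 3.00 ± 0.12 (SE; limma, adjusted p = 2.9e-26). Maob was lower in NZB/BINJ, 5.19 ± 0.08 against 8.78 ± 0.15 (SD, n = 2 each; difference -3.59 ± 0.14), as were the dynein chain Dnah8 (-3.53 ± 0.15), the aminopeptidase Rnpep (-3.27 ± 0.15), the iron-sulfur cluster scaffold Nfu1 (-3.00 ± 0.22), Lactb2 (-2.92 ± 0.19) and the phosphatase Phospho1 (-2.89 ± 0.24). St8sia1 was higher by 3.57 ± 0.18, Wfdc17 by 2.76 ± 0.53, 1700006J14Rik by 2.73 ± 0.20 and Ugt8a, which makes galactosylceramide, by 2.54 ± 0.19. These SEs rest on the spread pooled over all groups, and the NZB/BINJ arrays often lay further apart. Their SD was 0.79 for St8sia1, 0.66 for Wfdc17, 0.74 for 1700006J14Rik and 0.60 for Ugt8a. For the lower genes it was 0.74 for Nfu1, 0.67 for Phospho1, 0.42 for Dnah8, 0.32 for Lactb2 and 0.14 for Rnpep. The small nuclear RNA Rnu12 was higher by 3.11 ± 0.71, a call lost without NZW/LacJ replicate 1 (2.20). In total 6011 probe sets were higher and 5317 lower (53.1% higher), 177 and 805 of them at least 2-fold, against 13427 at an unadjusted p under 0.05. The median difference over all probe sets was 0.10, and centring on a common median moved it to -0.03 and the share of higher calls to 30.5%; over the 81 arrays, centring moved single arrays by up to 0.13. Without NZW/LacJ replicate 1 the share of higher calls was 35.9%. NZB/BINJ replicate 1 had the narrowest interquartile range of the 81 arrays, 2.10, and NZW/LacJ replicate 1 the widest, 2.86. The total of 11328 became 4378 without NZB/BINJ replicate 1, 4157 without NZW/LacJ replicate 1, 890 with the arrays of these strains alone, 4613 with the cell-cycle mean as a covariate and 1442 with the interquartile range as a covariate.

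Cell-cycle genes were lower in NZB/BINJ as a group (camera, adjusted p = 0.000387; adjusted p = 0.662 with an estimated correlation; 0.000149 to 0.662 over 9 alternatives), with 12 of 17 lower (13 adjusted over the list alone), Bub1 at -2.09 ± 0.30 and Pcna at -1.46 ± 0.28. Of 9 azurophil genes 1 was higher and 2 were lower (1 and 2 adjusted over the list alone), with a median of -0.02 (list adjusted p = 0.521). Ms4a3 was lower with -1.45 ± 0.24, and so was Gusb, a lysosomal enzyme, with -0.86 ± 0.12. Interferon-stimulated genes were lower (adjusted p = 0.0262; adjusted p = 0.662 with an estimated correlation; 0.00387 to 0.662 over 9 alternatives), with 10 of 17 lower (10 adjusted over the list alone), Ifit3 at -1.61 ± 0.36 and Oasl2 at -1.61 ± 0.24. Class II histocompatibility genes were higher (adjusted p = 0.0337; adjusted p = 0.662 with an estimated correlation; 8.2e-05 to 0.662 over 8 alternatives), with 6 of 9 higher (7 adjusted over the list alone), H2-Ea at 1.01 ± 0.16 and the class II activator Ciita at 0.62 ± 0.11. Immediate early and stress genes were higher (adjusted p = 0.0250; adjusted p = 0.662 with an estimated correlation; 1.3e-06 to 0.662 over 9 alternatives), with 7 of 13 higher (7 adjusted over the list alone), Egr1 at 1.56 ± 0.21 and Fosb at 0.89 ± 0.17. Of 9 B-cell markers 6 were higher (7 adjusted over the list alone), Cd79a by 0.77 ± 0.21 and Vpreb3 by 0.69 ± 0.15, while the list as a whole was not called (adjusted p = 0.112). Monocyte and macrophage markers gave 4 of 9 higher and 0 lower in limma (5 and 1 adjusted over the list alone), with a median of 0.32 and 6 at an unadjusted p under 0.05. Erythroid markers gave 3 of 5 higher (3 adjusted over the list alone), with a median of 0.33. Neither list was called as a whole (adjusted p = 0.351 and 0.439). Of 9 T and NK cell markers 3 were higher and 2 lower (4 and 2 adjusted over the list alone), the lower ones being Cd3d (-2.61 ± 0.19) and Cd3g (-1.78 ± 0.26). Of the 4 sex-linked genes 1 was higher and 3 were lower (1 and 3 adjusted over the list alone), among them the Y-linked Eif2s3y (-1.49 ± 0.23). Among probe sets with a mean of at least 7 the cell-cycle (0.103) and interferon (0.459) calls were lost. The interferon and class II calls were lost under quantile normalization (0.0514 each), and the interferon (0.145), class II (0.463) and immediate early (0.482) calls without NZB/BINJ replicate 2, as well as without NZW/LacJ replicate 2 (0.153, 0.153 and 0.0535).

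Of the genes in other lists, some kept their call in this pair when any 1 of the 4 arrays was left out and others did not. Of 13 inflammasome genes 5 were higher and 3 lower (6 and 3 adjusted over the list alone). Nlrp1b was higher by 1.86 ± 0.19 and Il1b, the gene of interleukin-1 beta, by 1.32 ± 0.28, while Casp1, the enzyme that processes it, was lower with -1.15 ± 0.21. Inhibitory and Fc receptors gave 5 higher and 4 lower of 14 (5 and 4 adjusted over the list alone), with Lilrb4a at 1.08 ± 0.13, Siglece at 0.87 ± 0.11 and the inhibitory Fc receptor Fcgr2b at -1.05 ± 0.12. Class I histocompatibility genes gave 1 higher and 4 lower of 10 (1 and 4 adjusted over the list alone), with H2-T24 at -2.35 ± 0.18 and H2-Q10 at -2.26 ± 0.19, and specific granule genes 1 higher and 3 lower of 12 (1 and 3 adjusted over the list alone), with Orm1 at -2.06 ± 0.27 and the integrin Itgb2l at -1.26 ± 0.13. Of 9 guanylate-binding and immunity-related GTPases 1 was higher and 1 lower (1 and 0 adjusted over the list alone, limma; 5 had an unadjusted p under 0.05). Gbp7 was higher by 1.38 ± 0.23, while Gbp9 (-0.63 ± 0.24) was not called without NZW/LacJ replicate 1 (-0.50) and changed sign without NZB/BINJ replicate 1 (0.046). With the arrays of these strains alone Lilrb4a, Egr1, Fosb, H2-Ea, Ciita, Cd79a, Vpreb3 and Eif2s3y kept their values but were not called. With the interquartile range as a covariate Rnu12 (2.87), Pcna (-0.53), Ciita (0.25), Casp1 (-0.57), Fosb (0.59) and Vpreb3 (0.32) were not called. Median, mean and test differed in sign for the T and NK cell list, with 0.25, -0.31 and a lower direction, and its adjusted p was 0.708.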

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

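The correlations of the cell-cycle level with azurophil genes and with erythroid and B-cell markers, the comparison with the classical range, the use of the cell-cycle level and of the array's interquartile range as covariates, and the condition on the NZW/LacJ arrays were chosen only after the result was seen.

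Among the 5 arrays of C57BL/6J, replicate 1 lay far from the others in 5 measures, where its gap to the nearest array took up an unusually large part of the whole range. Coro2a was 8.16 in this array and 8.55 in the nearest one, and Pi16 was 10.15 against 10.51. The mean of the glutathione and redox list was 8.14 against 8.30, that of the eosinophil markers 6.24 against 6.11, and that of the basophil and mast cell markers 5.80 against 5.69. In all, 101 sets of C57BL/6J values were examined, and chance marks about 1 in 20, which is about as many as were found, although all 5 fell on the same array and the sets are not independent. Among the wild-derived strain means of the 20 named genes, Stfa3 in WSB/EiJ, at 7.67 against 5.09 in the nearest strain, was the 1 value far from the others.

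Cell-cycle genes varied together between strains, with an SD of the list mean of 0.68. A narrower value range of some arrays is argued against as the whole cause, since 95.1% of that SD was left with the interquartile range of each array as a covariate, although the list mean was related to that range over the 40 strains (r = 0.404, permutation p = 0.00942, adjusted 0.0141; rho = 0.453, permutation p = 0.00320, adjusted 0.00480; r = 0.429 without NON/ShiLtJ and NOR/LtJ, the farthest strains). Erythroid or B-lineage precursors, which a sort on Ly6G would remove, are argued against by their markers (r = -0.0849, permutation p = 0.609, adjusted 0.609, upper end of the interval 0.233; rho = -0.0707, permutation p = 0.665, adjusted 0.665; r = -0.109 without the same strains), whose highest means were 7.11 for Slc4a1 and 6.95 for Cd79b. A larger share of immature granulocyte precursors is a candidate explanation. The mean of Mpo, Elane, Prtn3, Ctsg and Ms4a3, all genes that granulocytes themselves make, was related to the cell-cycle level. Here r was 0.791 and rho 0.781, each with a permutation p of 1e-05, the smallest possible here, and 3e-05 adjusted over the 3 relations. Without NON/ShiLtJ and NOR/LtJ r was 0.778. This mean leaned on Ms4a3, whose SD over strains was 0.63 against 0.14 to 0.21 for the others. Gene by gene, r was 0.909 for Ms4a3, 0.481 for Mpo, 0.480 for Elane, 0.338 for Prtn3 and 0.117 for Ctsg. The other measured azurophil genes were not set against the cell-cycle level. Faster division at an equal share of precursors was not tested and stays open. Markers of monocytes and of the remaining cell types were not set against the cell-cycle level.

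Of 10816 probe sets with a mean of at least 7, more lay far below the classical range than far above it in PWD/PHJ (52 and 19), CAST/EiJ (43 and 21), JF1/Ms (50 and 28) and MSM/Ms (42 and 26), and as many in WSB/EiJ (6 and 6). The median ratio of below to above, with 1 added to each count, was 1.88 in the first 4 strains; classical strains taken 1 at a time against the others had at most 5 below and 3 above, too few for a ratio to compare with. Sequence differences from the reference strain under the array probes could give such a ratio, but no probe sequences or variants were used here, so this stays open. True differences of transcript level between the origins stay open as well, and these data do not tell them apart. A random choice of 5 strains is argued against as the source of the 3039 calls between origins. Of 100 splits of the strains 1 gave as many, the real one. The highest other gave 617, a split that put 3 of the 5 wild-derived strains on 1 side. The splits treat the strains as independent, so they cannot separate origin from ancestry that some of the 5 may share.

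NZB/BINJ and NZW/LacJ differed at 11328 probe sets with the spread pooled over all groups, against 661, 425 and 1385 in the other pairs, but with the arrays of each pair alone they differed at 890, against 297, 1185 and 815, and the NZB/BINJ arrays had the largest residual SD of all arrays, 0.216. Without NZB/BINJ replicate 1, whose interquartile range was the narrowest, 4378 were called, but without NZW/LacJ replicate 1, whose range was the widest, 4157 were, so 1 deviating NZB array is not singled out as the source. With the interquartile range as a covariate 1442 were called: the median absolute difference went from 0.307 to 0.165, the SD of the differences from 0.479 to 0.343 and their median SE from 0.142 to 0.162, so differences shrank more than the error grew, while quantile normalization left 7727 calls with an SD of 0.435. A narrower value range of the NZB arrays may therefore account for part of the calls, and it cannot be told apart from a true wide difference between these strains, because the range differs between the groups themselves.

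A random grouping of the arrays is argued against as the source of the count of 13964 probe sets called over strains. Of 100 splits of the arrays into groups of the same sizes 1 gave as many, the real one, and the highest other gave 218. Single calls can still be false at an adjusted p under 0.05. The splits also cannot separate the strain from handling that the arrays of 1 group may have shared.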

How the results depend on the processing

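The cell-cycle mean and the interquartile range as covariates, leaving out both NZB/BINJ arrays, and the list tests under quantile normalization, a common median, the replicate block and left-out arrays were chosen only after the result was seen. Under every alternative other than left-out arrays the count over strains stayed between 9427 and 14086, and that with a 2-fold range between 4604 and 6502. Except where stated below, counts stayed within 1.5 times their value.

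For wild-derived against classical strains 1971 probe sets were called without JF1/Ms and 1796 without MSM/Ms, with fewer strains in the test; the other alternatives gave 2037 to 4049. The share of higher calls was 43.7% among probe sets with a mean of at least 7. Against C57BL/6J, dropping the minimum difference by construction raised the median count to 2155, the lowest to 661 and the highest to 11120.

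With a difference of at least 1 the pairs gave by construction fewer calls: 136 for C57BL/10J with C57BL/6J, 122 for the CBA substrains, 283 for NOD/ShiLtJ with NOR/LtJ and 982 for NZB/BINJ with NZW/LacJ. With the arrays of a pair alone the counts were 297, 1185, 815 and 890, and with the cell-cycle mean as a covariate, for which its own list members were left out as named genes, 117, 116, 82 and 4613. Of these last, 79, 97, 70 and 4464 were also called without the covariate, and the median SE grew 1.33, 1.19, 1.53 and 1.14 times. For NZB/BINJ with NZW/LacJ, 6331 were called among probe sets with a mean of at least 7, where fewer were tested, and 1442 with the interquartile range as a covariate. For the remaining changes the cause was not tested. Over the alternatives other than left-out arrays the share of higher calls lay between 48.7% and 94.1%, 52.6% and 74.6%, 32.9% and 85.2%, and 18.0% and 53.0% in the 4 pairs.

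Of the lists called between origins, in C57BL/10J, in CBA/J, in NOD/ShiLtJ and in NZB/BINJ (4, 4, 3, 4 and 4), an estimated correlation left 0, 1, 1, 1 and 0 called by limma's camera. Over all lists, whether called before or not, 2, 5, 1, 3 and 0 had an unadjusted p under 0.05 with it. Probe sets with a mean of at least 7 gave 1 between origins, 1 in CBA/J and 2 in NZB/BINJ. Quantile normalization gave 2 between origins, 7 in C57BL/10J and 1 in CBA/J, and the replicate block 7 in C57BL/10J. The cause was not tested. No called list changed direction in any alternative.

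Leaving out 1 array at a time, with the lone array left in a group assumed to vary like other groups, gave 13467 to 14966 calls over strains and 6018 to 7088 with a 2-fold range. Between origins it gave 2900 to 3611, against C57BL/6J a median of 347 to 383, a lowest count of 66 to 143 and a highest of 729 to 1505. The pairs gave 123 (without C57BL/10J replicate 3) to 999 (without C57BL/10J replicate 1), 124 to 214 (without CBA/J replicate 1 and 2), 451 (without NOD/ShiLtJ replicate 1) to 1621 (without NOR/LtJ replicate 1) and 4157 (without NZW/LacJ replicate 1) to 12835 (without NZB/BINJ replicate 2). Lists called numbered 3 to 6 between origins, 2 to 5 in C57BL/10J, 1 to 3 in CBA/J, 2 to 6 in NOD/ShiLtJ and 1 to 6 in NZB/BINJ.

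The results of single named genes numbered 331. Those of the strain F test are SDs of strain means, recomputed for each of the 81 left-out arrays. An SD cannot change sign, so these values count as keeping direction by construction. The totals therefore say little about how stable the directions of differences are. Under alternatives 13622 values were computed: 13076 kept direction and call, 541 kept direction but were not called, and 5 changed sign. All 5 were between NZB/BINJ and NZW/LacJ: Mmp8 at 0.0069 under quantile normalization, Il10ra at 0.14, Cd2 at -0.0055 and Prss34 at -0.057 with the interquartile range as a covariate, and Gbp9, which ranged from -1.30 without NZB/BINJ replicate 2 to 0.046 without replicate 1. The cause was not tested. Of the 541, 222 came from leaving out 1 array, 71 from the cell-cycle covariate, 70 from the arrays of a pair alone, 46 from the interquartile range, 31 from quantile normalization and 25 from a common median.

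Replicate numbers do not pair the samples: over 595 pairs of 35 groups the correlation of like-numbered deviations had a median of 0.004. It ran from -0.50 to 0.51, with 24.9% over 0.1 and 24.9% under -0.1. For the 4 pairs of strains it was -0.22, -0.05, -0.13 and -0.21. With the replicate block 13465 probe sets were called over strains, 6127 with a 2-fold range, 3043 between origins, 654, 433, 1381 and 11265 in the pairs, and a median of 388 against C57BL/6J, all within 1.5 times the counts without it. The 10816 of 24922 probe sets with a mean of at least 7 held 9182 of the 13964 calls over strains. Signal over background was not measured, so what it limits among the dimmer ones is unknown.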

Other observations

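The condition on histone genes in the test of neighbouring genes, and the comparisons of titled C57BR with single strains, were chosen only after the result was seen.

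In 5 groups the title and the background label name different strains, and profiles were set against the other groups by the correlation, across genes, of strain means minus the mean over strains; genes are not independent replicates. Titled BPL carries the label BALB/cByJ and lay nearest to P/J (r = 0.292). Titled BTBR carries BPL/1J and lay nearest to NON/ShiLtJ (0.513), and titled Balb carries BTBR T+ tf/J and lay nearest to C3H/HeJ (0.541). The labels of titled BPL, titled BTBR and titled Balb thus hold the same names as the titles in another order. Titled DBA2 carries DBA/1LacJ and lay nearest to CBA/J (0.262). Titled C57BR carries CBA/CaJ, a label that another group has as well, and lay nearest to C57BL/6J (0.50). Its correlation was 0.205 with C57L/J (668) and -0.157 with the other group labelled CBA/CaJ. In limma with Benjamini-Hochberg adjustment, titled C57BR differed from CBA/CaJ at 1756 probe sets, 360 of them at least 2-fold, from C57BL/6J at 669, 140 of them at least 2-fold, and from C57L/J (668) at 2896, 371 of them at least 2-fold. Nearness may also follow the cell-cycle level, which was not tested. The mean of that list was 9.16 in titled BTBR and 9.49 in NON/ShiLtJ, and 9.05 in titled Balb and 9.01 in C3H/HeJ. It was 7.39 in titled C57BR and 7.25 in C57BL/6J, 7.52 in titled BPL and 7.11 in P/J, and 8.30 in titled DBA2 and 8.92 in CBA/J. No label was changed on the basis of these profiles.

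Genes called between close relatives were tested for lying next to each other, as they would where relatives differ in a few chromosome segments. Neighbour order of 19675 genes came from assembly GRCm38.p6. Among the genes called between C57BL/10J and C57BL/6J, 11.8% had a called neighbour, against at most 9.78% in 1000 random placements, and for CBA/J and CBA/CaJ 12.7% did, against at most 9.67%, so 2 of the 3 pairs lay above every placement. For NOD/ShiLtJ and NOR/LtJ the share was 14.7%, and 5 of 1000 placements were as large. Without 24 called histone genes, which lie in clusters, the C57BL/10J share was 8.69%, and 9 of 1000 placements were as large. Segments that differ between the relatives may therefore account for part of the CBA calls, while for C57BL/10J neighbouring histone genes with a shared level are another candidate source, and the data leave this open.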
